A study of Mus musculus with 4 samples.

How the data were processed

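Small RNA libraries were made from the livers of 15-week-old C57BL/6 mice, 2 controls and 2 given thioacetamide (TAA), from total RNA isolated with an miRNeasy kit and with the TruSeq small RNA kit, per the labels' protocols. The deposited files hold raw read counts per mature miRNA, 1 file per library. Reads were aligned with Bowtie to mm10 and counted with HTSeq, per the submitters' processing notes. Their versions and settings, adapter trimming, the miRNA annotation release and the treatment of reads that match several loci are not given in the sources used here. The row for reads aligned at several places holds 0 in all 4 deposited count files. Counts of miRNAs with identical or overlapping sequences, such as miR-486a-5p and miR-486b-5p or miR-199a-3p and miR-199b-3p, are therefore uncertain.

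Each file holds 1907 mature miRNAs and 5 summary rows that name no miRNA, which were kept out of library sizes and tests. Reads aligned outside the annotated miRNAs made up 23.9% and 22.8% of reads in the controls and 24.3% and 26.4% in TAA-treated liver. Reads not aligned made up 7.11% to 8.49%, and ambiguous reads at most 0.00143%. The remaining 65.4% to 68.7% were miRNA counts, 42609845 to 48878003 per library, so that 1 CPM corresponds to between 42.6 and 48.9 counts. Shares have 95% Wilson intervals. Reads carried no stated molecular identifiers, so intervals cover counting error only. Between 993 and 1052 miRNAs were detected per library, and 651 had no counts in any.

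Samples were grouped by the treatment in the labels. The replicates were compared first: a chi-square test of counts gave 237 per degree of freedom between the controls and 324 between the TAA libraries, above read-sampling noise, so neither pair looked like copies of 1 library. That does not tell repeat libraries of 1 sample from separate animals, and all 4 libraries were used as the labels list them. The design text calls them biological replicates without naming animals. Batches are not given in the labels.

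Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM normalization, quasi-likelihood F test), with Benjamini-Hochberg adjustment over the 644 miRNAs kept, which hold 99.997% of counts, and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 0.191. miRNA lists were tested with camera at a preset correlation of 0.01, adjusted over the 11 lists with at least 3 tested members, and again with an estimated correlation and with fry. The 15 lists were hepatocyte, epithelial, mesenchymal, pro-fibrotic, anti-fibrotic, leukocyte, erythroid, endothelial, miR-17 cluster, miR-34 family, let-7 family, Dlk1-Dio3, H19-Igf2, muscle and pancreas miRNAs. Some share members, such as 5 between the hepatocyte and anti-fibrotic lists and 5 between the mesenchymal and pro-fibrotic lists. Arm ratios were log2 of the 5p over the 3p count, each plus 0.5, tested with limma 3.58.1 in hairpins with a mean of at least 20 counts in each arm.

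The groups, the tests, the lists, the alternatives and the rule for naming miRNAs were fixed before the data were examined. The rule takes up to 10 miRNAs per direction with the largest log2 fold change among those past the threshold whose libraries did not overlap and whose higher group reached 10 CPM, the 5 most abundant miRNAs, the 3 members of each list with the smallest p with its most abundant member, and up to 5 hairpins past the arm-ratio threshold. The text names 2 to 4 members per list where members were tested.

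Hairpin positions, host genes and the part of the gene were taken from the GENCODE annotation of GRCm38, which is mm10, for 1878 of the 1907 names. Names were matched directly or through older names in a RefSeq table of the same assembly. Host genes are those on the same strand as the hairpin.

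The edgeR procedure was tested on simulated counts with the means, library sizes and dispersions of this comparison. Of 621 simulated miRNAs tested, 95 changed 2-fold and 95 changed 4-fold; 58.9% and 95.8% were recovered, with 7 false calls among 154, and 0 calls when nothing changed. The arm-ratio test recovered 20 of 20 hairpins changed 4-fold among 150, with 1 false call. That simulation gave every hairpin the same median dispersion and drew its arms independently. The real arm ratios had unlike residual SDs, such as 0.025 for miR-29a and 1.62 for miR-382. The recovery therefore does not give the power of the real arm-ratio test. The edgeR simulation holds the spread of the fit and no differences between animals beyond it.

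Alternatives were other normalization factors, other filters on low counts, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library in turn, removing the most abundant miRNA, a fold-change minimum and other settings of the arm-ratio test. Removing the Dlk1-Dio3 miRNAs, with the list tests repeated on the rest, and a second distance for grouping hairpins were added after the data were seen. Target mRNAs and reads outside annotated miRNAs were not analysed here.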

Results

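MicroRNA abundance was measured by small RNA sequencing in the livers of 15-week-old C57BL/6 mice. The mice were either controls or had received thioacetamide (TAA), a hepatotoxin used to induce liver fibrosis in rodents, by intraperitoneal injection of 200 mg/kg 3 times a week for 10 weeks. Each group had 2 libraries, which the design text calls biological replicates. The libraries held 42609845 and 46224018 miRNA counts in the controls and 43836911 and 48878003 in TAA-treated liver, for 1907 mature miRNAs. The 95% Wilson interval of the largest share in any library extended by at most 0.0129 percentage points to either side, which covers counting error only. Values below are CPM, counts scaled to library size with TMM factors, as mean ± SD with n = 2 libraries per group, unless stated otherwise.

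In both groups the most abundant miRNAs included miR-192-5p and miR-148a-3p, which are members of the hepatocyte list. miR-192-5p took 24.3% and 24.5% of counts in the controls and 23.3% and 24.3% in TAA-treated liver. With miR-22-3p, miR-148a-3p, miR-30a-5p and miR-10a-5p it was among the 5 most abundant miRNAs, and the 5 leading miRNAs of each library took 56.7% to 59.6% of its counts. None of these 5 passed the test, with log2 fold changes of -0.16 (SE 0.09), -0.19 (SE 0.09), -0.24 (SE 0.09), -0.26 (SE 0.09) and 0.05 (SE 0.10) in that order. Without control 1, miR-148a-3p and miR-30a-5p passed it as lower. miR-122-5p, the hepatocyte-specific miRNA, took from 1.80% (TAA 1) to 1.998% (control 2) of counts. The shares themselves were given no test beyond edgeR's test of each miRNA; with 2 libraries against 2, the smallest two-sided p of an exact permutation test is 0.333.

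The comparison the series names is TAA-treated against control liver, and it asks which miRNAs change in TAA-induced fibrosis. The main change was a rise of miRNAs encoded in the imprinted Dlk1-Dio3 region of chromosome 12, whose non-coding RNAs are expressed from the maternal allele, mainly in embryonic tissue, placenta and brain. Of 644 miRNAs tested, 107 changed, 90 higher and 17 lower in TAA-treated liver, and 61 of the 90 that rose lie between positions 109571990 and 109743795 of chromosome 12 (GRCm38). In that interval of 171.8 kb, 67 miRNAs were tested, 61 rose and 0 fell, with a median log2 fold change of 3.58, or 12.0-fold. They come from 1 locus and many are arms of the same hairpin, so they are not 67 independent observations. The interval held 0.0202% and 0.0225% of counts in the controls against 0.318% and 0.244% in TAA-treated liver.

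**Figure D1:**
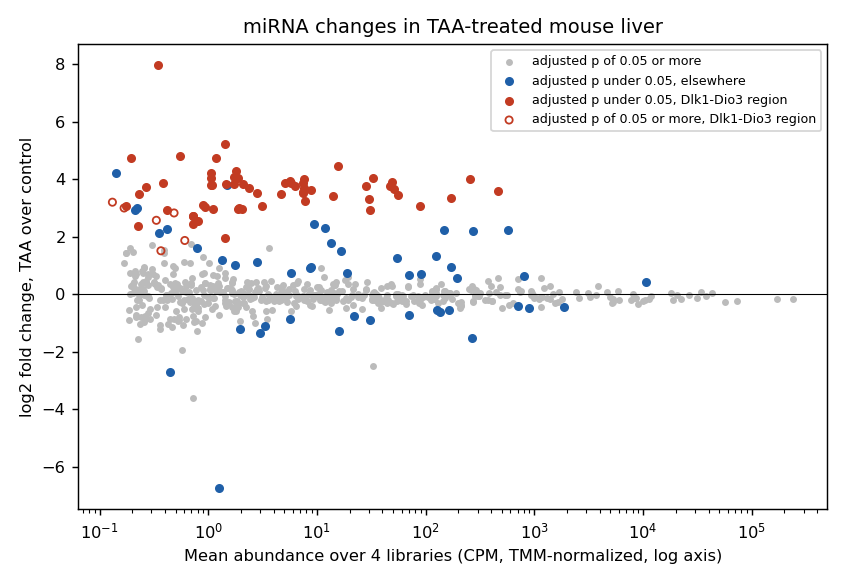
log2 fold change of each of the 644 tested miRNAs (vertical axis) against its mean abundance over the 4 libraries in CPM (horizontal axis, log scale). Red points are the 67 miRNAs of the Dlk1-Dio3 interval, filled for the 61 past the threshold, blue points are miRNAs elsewhere past the threshold and grey points did not pass it. The red points lie above 1.5 on the vertical axis, at low to middle abundance.

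The test was edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05; 165 miRNAs had an unadjusted p under 0.05. In all 107 miRNAs that changed, the libraries of the groups did not overlap, which chance gives in 33.3% of miRNAs not picked by a test. The test that picked the 107 favours such separation, so this adds no support of its own. Of those that rose 80, and of those that fell 7, changed at least 2-fold. The counts depended on the libraries: 54 miRNAs changed without TAA 1 and 49 without TAA 2, and those that fell numbered 3 and 2 there, against 29 without control 1 and 33 without control 2. With upper-quartile factors, which moved the median log2 fold change of all miRNAs to -0.17, 83 rose and 32 fell, so that 72.2% of the changed miRNAs were higher against 84.1% with TMM. Library size alone moved that median to 0.12, where 107 rose and 12 fell, so that 89.9% of the changed miRNAs were higher.

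All 10 miRNAs with the largest increases under the naming rule came from the Dlk1-Dio3 interval. miR-376b-3p rose from 1.37 ± 0.61 to 30.1 ± 8.43 CPM (log2 fold change 4.45, SE 0.35, edgeR adjusted p = 5.49e-05), at 109723458 to 109723539, outside annotated genes on its strand. miR-541-5p rose from 29.8 ± 10.1 to 482 ± 102 CPM (log2 fold change 4.02, SE 0.27, adjusted p = 3.22e-05) and miR-409-3p from 3.74 ± 1.12 to 62.2 ± 16.2 CPM (log2 fold change 4.05, SE 0.29, adjusted p = 3.62e-05). Both hairpins lie in introns of Mirg, a long non-coding RNA that hosts many miRNAs, at 109742409 to 109742498 and 109743158 to 109743236. The other 7 were miR-379-3p, miR-485-3p, miR-381-3p, miR-127-5p, miR-337-5p, miR-409-5p and miR-299a-3p, with log2 fold changes of 3.77 or more. One miRNA of the interval had no counts in either control library, and its fitted change is not quoted.

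Of the 43 Dlk1-Dio3 miRNAs listed before the data were examined, 40 were tested, 38 rose and 0 fell (40 rose adjusted over the list alone). Their median log2 fold change was 3.60, with a range of 1.87 to 5.24, and the libraries did not overlap in any of the 40. The most abundant was miR-411-5p, which rose from 71.0 ± 9.05 to 851 ± 140 CPM (log2 fold change 3.58, SE 0.17, edgeR adjusted p = 1.54e-05). miR-127-3p rose from 9.19 ± 0.34 to 101.5 ± 11.8 CPM and miR-434-3p from 30.6 ± 4.25 to 313 ± 62.0 CPM. This was the only one of 11 lists past the threshold of camera (adjusted p = 3.63e-68), which compares a list with the other miRNAs at a preset correlation of 0.01. With an estimated correlation its p was 0.0318 and its adjusted p = 0.350, and fry, which tests whether members move one way on balance, gave p = 0.00825 and adjusted p = 0.0907, so that 0 lists passed either. Without TAA 1 or without TAA 2, 30 members rose in each case. With limma-voom, and also with no filter on low counts, 6 lists passed camera: Dlk1-Dio3, leukocyte, hepatocyte, anti-fibrotic, miR-34 family and erythroid.

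**Figure D2:**
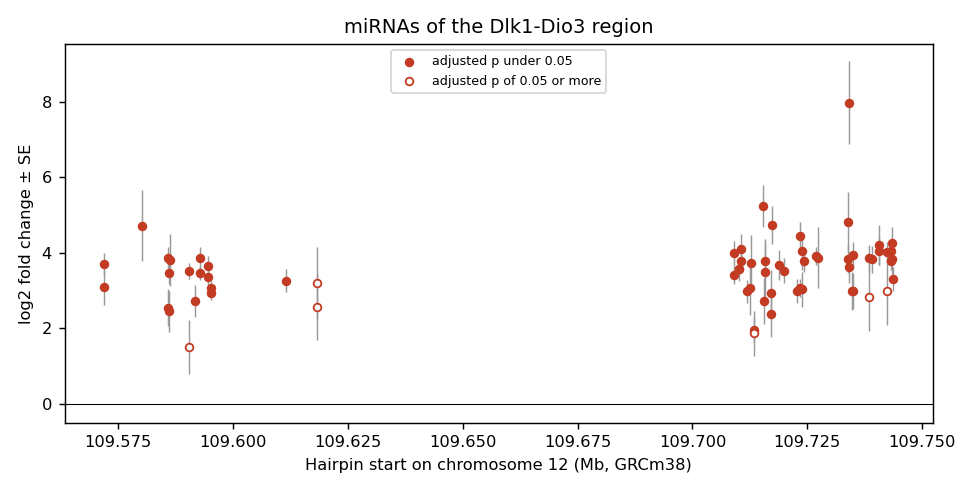
Map of the 67 tested miRNAs of the Dlk1-Dio3 interval, with the hairpin start on chromosome 12 in Mb (GRCm38) on the horizontal axis and the log2 fold change, TAA over control, on the vertical axis. Bars are ± SE of the edgeR fit from 2 libraries per group, and filled points passed the threshold. All 67 lie above 0; the topmost point is the miRNA without counts in the controls, whose fitted value is no estimate of size.

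Outside the interval, 29 miRNAs rose and 17 fell, and how many passed depended on the interval itself. With the Dlk1-Dio3 miRNAs removed before normalization, an alternative chosen after the data were seen, 7 rose and 5 fell. Those 12 were miR-129-2-3p, miR-129-5p, miR-149-5p, miR-150-5p, miR-155-5p, miR-34a-5p and miR-34c-5p among the higher, and miR-10b-5p, miR-210-3p, miR-383-5p, miR-470-5p and miR-871-3p among the lower. Adjusting the original p-values over the 577 miRNAs outside the interval alone gave 5 and 5. In the same fit 5 of the 10 lists then tested passed camera, which compares a list with the other miRNAs, against 1 with the interval included: leukocyte, miR-34 family, erythroid, pro-fibrotic and hepatocyte. With an estimated correlation and with fry, 0 of the 10 passed. Without TAA 1 or TAA 2, 10 and 3 rose outside the interval, and with upper-quartile factors 19.

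Among the miRNAs that fell, miR-10b-5p had the largest decrease under the naming rule, from 397 ± 107 to 136 ± 9.78 CPM (log2 fold change -1.54, SE 0.19, edgeR adjusted p = 0.000666). Its hairpin lies at 74726070 to 74726137 of chromosome 2, in introns of Hoxd3 and Hoxd4. miR-871-3p fell from 22.8 ± 0.24 to 9.38 ± 0.016 CPM (log2 fold change -1.28, SE 0.17, adjusted p = 0.00113) and lies between genes on chromosome X, at 66810428 to 66810504. miR-210-3p, which is induced by hypoxia, fell from 39.9 ± 1.59 to 21.2 ± 2.45 CPM (log2 fold change -0.91, SE 0.17). The others were miR-676-5p, miR-141-3p, miR-676-3p, miR-455-5p, miR-29b-3p, miR-29c-3p and miR-203-3p, with log2 fold changes from -0.77 to -0.43. Without TAA 1 and without TAA 2, miR-871-3p alone of these 10 passed the threshold, and those 7 also did not pass with the Dlk1-Dio3 miRNAs removed.

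Of the 10 leukocyte miRNAs, 5 rose and 0 fell (7 rose adjusted over the list alone), with a median log2 fold change of 0.63. miR-150-5p, a miRNA of mature lymphocytes, rose from 71.0 ± 5.13 to 180 ± 11.0 CPM (log2 fold change 1.34, SE 0.14, edgeR adjusted p = 0.000241). miR-155-5p, which is induced on activation of immune cells, rose from 5.97 ± 0.37 to 11.5 ± 0.70 CPM and miR-342-3p from 68.8 ± 3.60 to 111 ± 17.6 CPM. miR-142a-5p, the most abundant member, measured 935 ± 324 CPM in control and 1389 ± 140 CPM in TAA-treated liver (adjusted p = 0.138). The list did not pass camera (adjusted p = 0.0956; p = 0.403 with an estimated correlation). It passed without the Dlk1-Dio3 miRNAs (adjusted p = 2.17e-07; p = 0.0971 with an estimated correlation), where 2 members rose, and without control 2 (adjusted p = 0.00544), where 9 members rose, while 3 rose without control 1 and 1 without TAA 1 or without TAA 2.

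Of the 6 tested miR-34 family members, which are transcriptional targets of p53, 3 rose and 0 fell (4 rose adjusted over the list alone), with a median log2 fold change of 1.39. miR-34a-5p rose from 32.5 ± 8.58 to 77.2 ± 5.62 CPM (log2 fold change 1.25, SE 0.21, edgeR adjusted p = 0.00367) and miR-34c-5p from 8.63 ± 0.79 to 24.5 ± 5.59 CPM (log2 fold change 1.505, SE 0.22, adjusted p = 0.00172). miR-34b-3p rose from 0.14 ± 0.067 to 0.69 ± 0.23 CPM. The list did not pass camera (adjusted p = 0.0956; p = 0.298 with an estimated correlation), but passed without control 1 (0.00829), without control 2 (0.0313) and without the Dlk1-Dio3 miRNAs (1.16e-06; p = 0.0753 with an estimated correlation). Without TAA 1 and without TAA 2, 1 member rose in each case, and miR-34a-5p did not pass.

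All 5 erythroid miRNAs rose, with a median log2 fold change of 2.23, but the rise rested largely on TAA 2. miR-486a-5p measured 202 ± 61.7 CPM in control and 948 ± 749 CPM in TAA-treated liver (log2 fold change 2.23, SE 0.51, edgeR adjusted p = 0.0199), and miR-144-5p 2.98 ± 0.97 and 15.98 ± 13.8 CPM. The 5 members were 3.53 to 4.42 times higher in TAA 2 than in TAA 1. Without TAA 2 the median log2 fold change was 1.03 and 0 of the 5 passed. The list did not pass camera (adjusted p = 0.0956; p = 0.438 with an estimated correlation); it did with upper-quartile factors, without control 1, control 2 or TAA 1, and without the Dlk1-Dio3 miRNAs (adjusted p = 7.04e-05; p = 0.187 with an estimated correlation), where 0 members passed. miR-486a-5p and miR-486b-5p come from overlapping hairpins on opposite strands of chromosome 8, the former in an intron of Ank1 and the latter in an intron of the antisense gene Gm15816, and how reads were divided between them is not given in the sources used here.

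**Figure D3:**
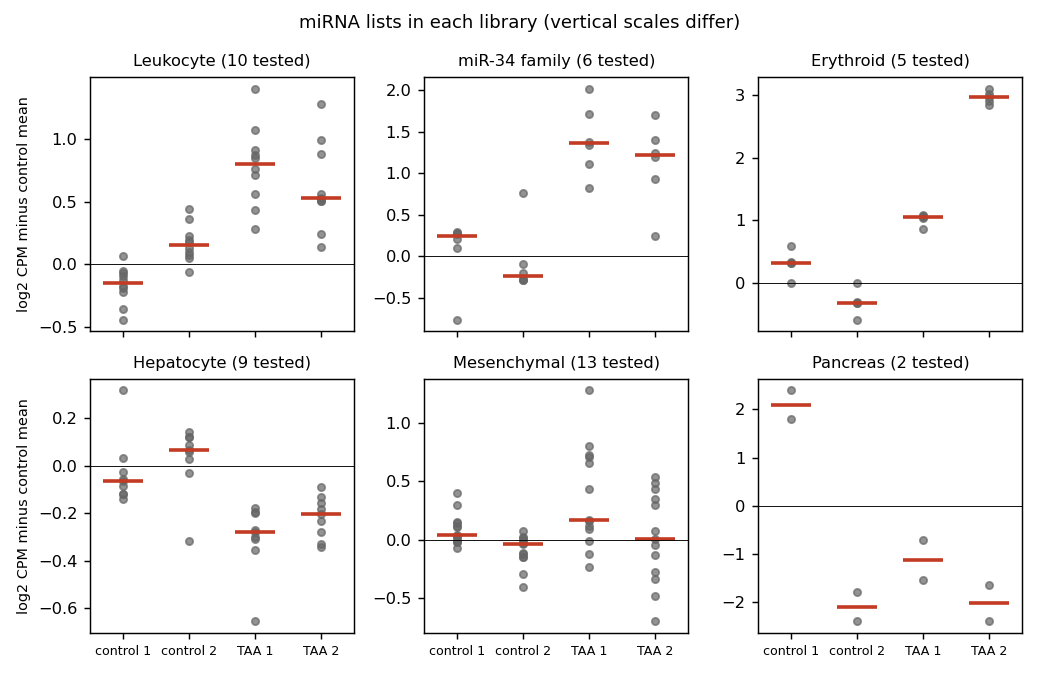
log2 CPM minus the mean of the control libraries (vertical axis, with a different scale in each panel) in each of the 4 libraries, for the tested members of 6 miRNA lists. Grey points are miRNAs and red bars their median. The 5 erythroid miRNAs are highest in TAA 2 and the 2 tested pancreas miRNAs in control 1.

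None of the 9 hepatocyte miRNAs passed the edgeR test, with a median log2 fold change of -0.24 that lay between -0.41 and -0.11 over the fits. With TMM factors, 8 of the 9 had lower CPM in both TAA libraries than in both controls. By share of all miRNA counts the groups overlapped in miR-192-5p, at 24.34% in TAA 2 and 24.33% in control 1. They also overlapped in miR-122-5p, at 1.84% in TAA 2 and 1.82% in control 1. miR-122-3p measured 1715 ± 147 CPM in control and 1372 ± 11.9 CPM in TAA-treated liver, and miR-101b-3p 9997 ± 1393 and 7964 ± 177 CPM. The list gave a camera adjusted p of 0.0956 (p = 0.378 with an estimated correlation), and 0.0219 without control 1, where 3 members fell and the anti-fibrotic list also passed; 1 member fell without control 2. Without the Dlk1-Dio3 miRNAs the hepatocyte list gave 0.0267 (p = 0.334 with an estimated correlation). Of the 17 miRNAs reported as anti-fibrotic, 5 of which are also in the hepatocyte list, 1 rose and 2 fell, with a median log2 fold change of -0.24 and a camera adjusted p of 0.0956 (p = 0.235 with an estimated correlation). miR-29b-3p fell from 152 ± 9.69 to 104 ± 7.33 CPM and miR-29c-3p from 1033 ± 2.32 to 736 ± 15.0 CPM. Both belong to the miR-29 family, which targets collagen mRNAs. The more abundant miR-29a-3p of that family, also in the list, did not pass. It had 246800 and 243030 counts in control and 223789 and 234371 in TAA-treated liver. miR-150-5p was the member of the anti-fibrotic list that rose. Without control 1, 6 anti-fibrotic members fell, and without TAA 1 or without TAA 2, 0 fell; 2 rose without control 2.

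Of the 15 miRNAs reported as pro-fibrotic, 3 rose and 0 fell, with a median log2 fold change of 0.12 that turned to -0.06 with upper-quartile factors (camera adjusted p = 0.734). The list passed camera without the Dlk1-Dio3 miRNAs (adjusted p = 0.00446; p = 0.155 with an estimated correlation), where 2 members rose. Without control 1, 5 members rose, without control 2, 2, and without TAA 1 or without TAA 2, 0. The median was 0.06, 0.15, 0.07 and 0.25 in those 4 fits. With all libraries, those that rose were miR-34a-5p, miR-155-5p and miR-214-3p, the last from 55.1 ± 5.93 to 86.6 ± 13.3 CPM. They are also in the miR-34 family, leukocyte and mesenchymal lists, in that order, so they are not separate results. The 2 that rose without the Dlk1-Dio3 miRNAs were miR-34a-5p and miR-155-5p. miR-21a-5p, the most abundant of the pro-fibrotic list, measured 32777 ± 6950 CPM in control and 34848 ± 1082 CPM in TAA-treated liver (log2 fold change 0.09, SE 0.14, edgeR adjusted p = 0.787). Of the 13 mesenchymal miRNAs, miR-214-3p rose and 0 fell (0 adjusted over the list alone). Without control 1, 4 members rose; without control 2, 0 rose and 1 fell; without TAA 1 or without TAA 2, 0 passed. The median log2 fold change was 0.07 and turned to -0.11 with upper-quartile factors, while camera gave the direction down at an adjusted p of 0.976. miR-143-3p, the most abundant member, had a log2 fold change of -0.04 (SE 0.14). miR-214-5p (log2 fold change 0.60, SE 0.18) and miR-199b-3p (0.55, SE 0.17) were higher without passing. In 5 of the 13 members both TAA libraries lay above both controls, and in 1 both lay below. The flat median therefore does not describe every member. miR-214-3p did not pass without either TAA library, without control 2 or with upper-quartile factors.

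Of the 8 miRNAs of the epithelial miR-200 and miR-183 families, 2 fell and 0 rose, with a median log2 fold change of -0.15 (camera adjusted p = 0.131). The median was -0.48 without control 2 and -0.43 without TAA 2; 1 member fell without control 1 and 0 without TAA 1 or without TAA 2. miR-141-3p fell from 87.6 ± 15.7 to 53.0 ± 2.31 CPM and miR-200c-3p from 7.21 ± 1.43 to 3.996 ± 0.39 CPM; their hairpins are neighbours on chromosome 6, at 124717914 to 124717985 and 124718322 to 124718390. Of the 9 let-7 family members, let-7e-5p rose from 158 ± 9.47 to 232 ± 11.9 CPM and 0 fell, with a list median of 0.01 that turned to -0.16 with upper-quartile factors (camera adjusted p = 0.775); without control 2, TAA 1 or TAA 2, 0 members passed. let-7f-5p, the most abundant member, had a log2 fold change of -0.03 (SE 0.10). None of the 9 tested miRNAs of the miR-17 cluster and its paralogs passed, with a median of -0.07 that turned to 0.05 with library size alone (camera adjusted p = 0.447); without control 2, 2 fell. With all libraries, miR-25-3p had a log2 fold change of 0.22 (SE 0.11) and miR-92a-3p, the most abundant, of 0.05 (SE 0.10). Neither endothelial miRNA passed; miR-126a-3p had a log2 fold change of -0.04 (SE 0.10) and miR-126a-5p of -0.17 (SE 0.12).

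Markers of tissues other than liver were measured in the same libraries. Of the 7 muscle miRNAs, 2 were tested and neither passed: miR-133a-3p had a log2 fold change of -0.59 (SE 0.24) and miR-499-5p of 0.20 (SE 0.59). The list summed to 3.92 and 4.82 CPM of library total in control and 3.17 and 3.56 CPM in TAA-treated liver. Of the 4 pancreas miRNAs, 2 were tested and neither passed (1 fell adjusted over the list alone). Without control 2, all 4 were tested and fell, with a median log2 fold change of -4.66, and the list passed camera (adjusted p = 1.73e-08). miR-375-3p reached 102.6 CPM of library total in control 1 and lay between 7.83 and 10.6 CPM in the other 3 libraries; it passed as lower in TAA-treated liver with upper-quartile factors, library size alone, no filter or without control 2. None of the 4 miRNAs of the H19-Igf2 locus had enough counts to be tested.

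The ratio of the 5p to the 3p arm was compared in 150 hairpins with at least 20 counts per arm on average. With limma, 0 hairpins changed, 5 had an unadjusted p under 0.05 and the smallest adjusted p was 0.668. The result depended on the setting: 1 hairpin (miR-376b) passed with at least 100 counts per arm, and 3 (miR-337, miR-673 and miR-376b) with a pseudocount of 5. Which hairpins passed also changed without control 1 or control 2. miR-376b, miR-337 and miR-673 lie in the Dlk1-Dio3 interval, where control ratios rest on few counts. miR-337-3p, for one, had 11 and 9 counts in control and 83 and 49 in TAA-treated liver. No other tool was run on these ratios.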

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

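The tests of muscle, neural and mesenchymal sources and of blood were chosen after the results they bear on had been seen; the comparison of pancreatic opposite arms was written before their counts were seen.

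Data not used in the comparison were listed here only where both TAA libraries lay above both controls. That order is therefore no support, and chance alone keeps groups of 2 and 2 from overlapping in 33.3% of cases. Reads aligned outside the annotated miRNAs averaged 25.4% ± 1.48 (SD, n = 2) of reads in TAA-treated liver and 23.4% ± 0.77 in control. TAA 1 at 24.3% lay close to control 1 at 23.9%. The 43 miRNAs of the Dlk1-Dio3 interval that the low-count filter left out, 21 of which had any count, summed to 138 counts in the TAA libraries (77 and 61) and 12 in the controls (7 and 5).

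The joint rise of the Dlk1-Dio3 miRNAs, with a list median of 3.60 on the log2 scale, was set against RNA from other tissues and cells. Muscle carried with the TAA-treated livers is argued against by the muscle list, whose summed CPM was not higher in TAA-treated liver (log2 of the highest TAA over the lowest control library -0.14). For neural tissue, a list of neural miRNAs gave a corresponding value of 0.27. That sum was led by miR-128-3p, with 1920 and 1849 counts in control and 1768 and 2504 in TAA-treated liver, so scarce members hardly move it. In control 1, control 2, TAA 1 and TAA 2, miR-124-3p had 0, 2, 0 and 5 counts and miR-9-5p 31, 48, 24 and 54. These scarce members argue against neural tissue, while the miR-129 members, also scarce, were higher in both TAA libraries than in both controls. The list was written after the top miRNAs had been seen, and miR-129, first left out of it, was added because miR-129-2-3p and miR-129-5p had risen. Growth in proportion of the mesenchymal cells already present would raise miRNAs made mainly by those cells alike. The mesenchymal list had a median of 0.066 with an SD of 0.41 over members. Its largest value was 0.90, below the smallest value of the Dlk1-Dio3 list, 1.87. Of its 13 members, 5 were higher in both TAA libraries than in both controls and 1 was lower. How far other cells make these miRNAs was not measured, so the list cannot exclude such growth as a part of the rise. A change of expression within liver cells, a cell type outside these lists, and differences between the animals other than TAA stay open and were not tested.

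The 5 erythroid miRNAs were higher in TAA 2 than in TAA 1 by a similar ratio, 3.53 to 4.42, as more blood in that liver could give. They are not 5 independent observations. miR-486a-5p and miR-486b-5p come from overlapping hairpins, and miR-144-3p, miR-144-5p and miR-451a from neighbouring hairpins on chromosome 11. Without TAA 2 their median log2 fold change was 1.03 (median SE 0.29), against 2.23 with it, and 0 of the 5 passed. Without TAA 1, which also leaves a single treated library, it was 2.91 at the same median SE of 0.29 and all 5 passed, so the calls ended with the smaller change and not with a larger SE. Blood in TAA 2 alone and a rise in both TAA livers cannot be told apart, since TAA 1 is then the only treated library. The bound of this test was made stricter after its value had been seen: by the first bound, which asked only for a median above 0.5 by more than its SE, blood in TAA 2 alone would have been argued against.

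Control 1 held more of the pancreas miRNAs than the other libraries. miR-375-3p, which is also made in other endocrine and epithelial cells, was 9.72 times higher there than in the next library. miR-216a-5p had 113 counts against 0, 10 and 0, miR-217-5p 125 against 0, 6 and 5, and miR-216b-5p 72 against 2, 2 and 1. Pancreatic tissue in that library is a candidate source and stays open. The opposite arms of the listed miRNAs summed to 38 counts in control 1 and 0, 4 and 2 in the others, a ratio of 9.77 to the highest (95% exact interval 3.52 to 37.7), but they come from the same hairpins, so any source of those precursors would raise them and they do not favour pancreas over another source. No biological explanation was tested, since the design names none for a single control.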

How the results depend on the processing

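The alternatives without the Dlk1-Dio3 miRNAs were chosen after the data were seen; the others were planned, and the cause of a difference was not tested unless given. With the preset correlation, each alternative fit that kept the Dlk1-Dio3 list left its camera result past the threshold, with a median log2 fold change between 3.32 and 3.85. Of 35 named miRNAs past the threshold, 16 passed in every alternative fit that tested them, 19 were lost at least once and 0 reversed. Outside the Dlk1-Dio3 interval, only miR-871-3p, miR-150-5p and miR-34c-5p were among the 16. The rest of the 16 lie in the interval and were not tested in the fit without it. Over all fits a named miRNA lost its call 78 times and gained it 28 times, and a list gained it 24 times. Leaving out a library gave 49 to 131 changed miRNAs, 47 to 98 higher, 2 to 33 lower, 3 to 34 higher outside the Dlk1-Dio3 interval, 30 to 39 Dlk1-Dio3 list members higher, 1 to 5 lists and 0 to 13 arm-ratio changes; a lone sample is then assumed to vary like the other group. Upper-quartile factors gave 32 lower, 19 higher outside the Dlk1-Dio3 interval and 2 lists. No filter gave 32 lower and 6 lists. A filter of 10 CPM in 2 libraries left only 282 miRNAs and 18 of the Dlk1-Dio3 list to test. It gave 41 changed, 36 higher, 5 lower, 14 higher outside the Dlk1-Dio3 interval and 18 Dlk1-Dio3 list members higher. The smaller number tested is not the whole of this. miR-203-3p, miR-455-5p, miR-29b-3p, miR-676-3p and miR-141-3p, among others, were still tested there and lost their calls. limma-voom gave 6 lists, and an estimated correlation and fry gave 0. A minimum of 2-fold left 7 lower. Without the Dlk1-Dio3 miRNAs 5 lists passed camera, 0 with an estimated correlation or fry, and 7 miRNAs were higher and 5 lower outside; adjusting the original p-values without them gave 5 and 5, so the Benjamini-Hochberg adjustment alone lowers the counts that far. Arm ratios gave 1 change with at least 100 counts per arm and 3 with a pseudocount of 5; limma's prior degrees of freedom were 3.52 in the reported fit and infinite with 100 counts and in all 4 fits without a library, which sets a single SD for every hairpin. The replicate numbers are not said to pair the samples. Over the tested miRNAs, the deviations of control 1 and TAA 1 from their group means correlated at -0.053. With 2 libraries per group the deviations of replicate 2 mirror these, so this is a single comparison. With the replicate block 110 miRNAs changed, 92 higher and 18 lower, and 0 arm ratios. miRNAs under about 1 CPM rest on few counts, where depth limits what can be called.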

Other observations

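These miRNAs and the grouping of hairpins by position were chosen after their values had been seen, and the test of the chromosome X group was too.

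On chromosome X, 6 tested miRNAs between positions 66777256 and 66814025 (GRCm38) were all lower in TAA-treated liver, with a median log2 fold change of -1.19. The hairpins lie between genes, in a group of miRNAs known mainly from testis. miR-871-3p, miR-470-5p, miR-741-3p and miR-881-3p fell, with log2 fold changes of -1.28 (SE 0.17), -1.11 (SE 0.21), -1.35 (SE 0.33) and -1.21 (SE 0.32), while miR-871-5p and miR-743b-3p did not pass the test. Of the 58 X-linked miRNAs tested elsewhere, 0 rose and 2 fell, with a median of -0.0025. When tested miRNAs with a single locus were grouped by hairpins within 50 kb of each other, 47 clusters held at least 3 of them and were tested. Camera placed 3 clusters past the threshold, 2 on chromosome 12 and this group (adjusted p = 0.00625). The group was singled out because its members had fallen in the same data, so this p is no independent evidence of a shared fall, and with an estimated correlation its p was 0.0687 and 0 clusters passed. At 10 kb there were 46 clusters, of which 3 passed with the preset correlation and 0 with an estimated one.

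miR-383-5p, from an intron of Sgcz on chromosome 8, fell to near absence: 112 and 102 counts in the controls against 2 and 0 in TAA-treated liver, a ratio of 112 (95% exact interval 30.5 to 928, counting error only). On chromosome 2, miR-129-2-3p rose from 0.20 ± 0.12 to 2.80 ± 0.42 CPM (log2 fold change 3.79, SE 0.43, edgeR adjusted p = 0.000333). miR-670-3p, from an exon of the same host transcript Mir670hg, had 1 and 0 counts in the controls and 14 and 12 in TAA-treated liver, a ratio of 24.9 (95% exact interval 4.09 to 1021). miR-10b-5p fell while miR-10a-5p, a close relative from another Hox cluster, had a log2 fold change of 0.05 (SE 0.10). miR-149-5p, from an intron of the heparan sulfate proteoglycan gene Gpc1, rose from 118 ± 1.96 to 226 ± 40.4 CPM (adjusted p = 0.00454). miR-3072-3p, 1 of the 29 that rose outside the Dlk1-Dio3 interval as defined, lies in an exon of Mirg just beyond its end.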
